A study of Homo sapiens with 7 samples.

How the data were processed

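H3K4me3, trimethylated lysine 4 of histone H3, was profiled by chromatin immunoprecipitation and sequencing in Jurkat cells, an established human line of T-cell acute lymphoblastic leukaemia. Per the labels' protocols, cells grown with 10% FBS were kept in suspension or in a gel of type I collagen (1.7 mg/mL) during 3 h, strained, crosslinked in 1% formaldehyde over 4 min and sonicated, and 30 µg of chromatin went into each immunoprecipitation. Libraries were sequenced on an Illumina NextSeq instrument, per the labels' protocols. Of the 7 samples, 3 were H3K4me3 libraries from suspension cells, 3 were H3K4me3 libraries from cells in collagen, and 1 was a control immunoprecipitation, which was not analysed here as a sample. Groups came from the treatment labels and replicate numbers from the sample titles.

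The authors deposited 1 peak list per H3K4me3 library, so peaks were called on each library and not on pooled replicates. Per the submitters' processing notes, the tools included BWA 0.7.12 and MACS2 2.2.7.1 and the genome build was hg19, whereas the file headers name MACS 2.1.2. Per the file headers, every library was compared with the same control of 26.6 M tags, in broad mode, with a q cutoff of 0.05 for strong and 0.1 for broad regions, an effective genome size of 2.70e+09 bp, no fragment model, a fragment length of 200 bp and all duplicate tags kept. The labels and headers do not say whether that control was input DNA or the control immunoprecipitation, so fold enrichment and local background are relative to a control of unstated kind. Per the file headers, the larger of each pair of datasets was scaled down to the smaller, and local background was estimated over 1000 and 10000 bp. The deposited signal is the pileup of extended tags at a peak, as a mean over the peak in broad mode. The deposited −log10 p and −log10 q values measure each peak against local background. The deposited fold enrichment is a ratio of pileup to local background and is the authors' own value for each peak. It was used here to describe, rank or filter peaks within a list, and to describe regions and libraries side by side. It was not tested between groups. Positions in the lists are 1-based. The last peak of chromosome 1 ended at 249201408, beyond the last gene end (248937099) in the GRCh38 gene table that was given, so that table was used only for the number of protein-coding genes on each chromosome, with none of its coordinates.

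Kept duplicates and a shared control bear on the values in different ways. PCR copies that were not removed can add to pileup, and any feature of the control, such as high coverage of repeated sequence, enters all 6 lists in the same way. A peak list records only what passed the caller's threshold, so a region missing from a list may still carry signal below it. Total tags (M, megatags) were 28.8 M, 28.1 M and 27.4 M in suspension replicates 1, 2 and 3, and 27.3 M, 29.7 M and 29.1 M in collagen replicates 1, 2 and 3. Local background is not a column of the deposited lists; it was derived here as (pileup + 1) / fold − 1, on the assumption that the caller added 1 to both terms of the ratio. The share of tags in peaks was estimated from mean pileup, peak length and the 200 bp fragment length, and is an approximation because the pileup was scaled. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals. They cover counting error only.

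The number of peaks, the genomic length under peaks, the median peak width and the tag totals were compared between groups as collagen minus suspension, with exact two-sided permutation tests of the difference in means. With 3 libraries against 3 there are 10 distinct splits and the smallest possible p is 0.1. Similarity was the Jaccard index of bases under peaks, and the mean within groups minus the mean between groups was tested over the same 10 splits. These 5 tests were adjusted together by the Benjamini-Hochberg method. Peaks of all libraries that overlapped by at least 1 bp were merged into regions, and a library was counted as having a region when a peak of its own overlapped it. Regions were counted as recurring in a group when at least 2 of its 3 libraries had them. A single region cannot pass a test of presence in 3 against 3 libraries, so counts were set beside those of the other splits. Chance overlap of a pair of lists was taken from 20 circular shifts of the shorter list within each chromosome. The region counting was tested on the real lists with the suspension peaks removed from 200 randomly chosen regions. When these were drawn from any region with a collagen peak, 136 were returned as collagen-only. When these were drawn from regions with peaks in at least 2 collagen libraries, 198 were returned as collagen-only. Both results follow from the definition, since a region with a peak in only 1 collagen library cannot be returned. They check the counting and not its sensitivity.

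Fixed before the data were examined were the comparisons of peak number, genomic length, region counts and similarity, with their tests. So were the rule for named regions and the alternative settings. The tests of median peak width and tag totals were not in that plan. Neither were the correlations with tag totals and gene numbers, the deciles, the core regions or the work on chromosome X. The rule took 5 regions from each of 3 sets, namely those recurring in collagen without a suspension peak, those recurring in suspension without a collagen peak, and the widest of those present in the most libraries. Within the former pair of sets, regions found in more libraries of the group came before others and were ranked by the mean within-list percentile of −log10 q. Planned results on promoters, and on 17 gene lists fixed in advance, were not run, since no annotation of hg19 was used here; peaks are given by position without gene names. The alternatives were a stricter threshold of −log10 q of at least 5, merging peaks within 1 kb, overlap of 50% of a region, presence in all 3 libraries, lists cut to their 2000 highest-scoring peaks, chromosomes 1 to 22 and X alone, a log2 scale with 1 added, the replicate number as a block, and leaving out each replicate in turn. Counts of regions recurring in only 1 of the groups, whatever the other group's single libraries held, were added after the data were seen, as were the wide regions present in 5 libraries and the work on long peak-free spans. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.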

Results

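Jurkat cells, a human T-cell acute lymphoblastic leukaemia line, were cultured in suspension or inside a gel of type I collagen (1.7 mg/mL) during 3 h, and H3K4me3, a histone mark found at active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing. The study concerns WDR5, a shared subunit of the complexes that methylate this lysine, and the passage of leukaemia cells through confined spaces. The comparison asks whether a short stay in a three-dimensional matrix changes where the mark lies. There were 3 libraries per condition, sequenced to between 27.3 M and 29.7 M tags, and a separate peak list for each. The labels do not say that replicates came from separate cultures, so the p-values set differences only against the spread between these libraries, which may be technical.

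H3K4me3 peaks from the 6 libraries merged into 16544 regions, and in the full lists nearly all regions recurring in collagen had a peak in at least 1 suspension library, mostly replicate 1. Of the 8708 regions with a peak in at least 2 of the 3 collagen libraries, 8686 had a peak in at least 1 suspension library, and 22 (0.253%, 95% interval 0.158 to 0.382) had none. In the other direction, 2958 regions had a peak in at least 2 suspension libraries, 9 of them had no collagen peak, and 2949 (99.7%, 99.4 to 99.9) had at least 1. A total of 2876 regions recurred in both conditions. These counts rest on single libraries: without suspension replicate 1 the collagen-only count was 6342, without collagen replicate 1 it was 11 and without collagen replicate 2 it was 7. The suspension-only count was 0 without either suspension replicate 1 or 2, 15 without collagen replicate 1 and 75 without collagen replicate 2, and the shared count was 6 without either suspension replicate 1 or 2. They also rest on settings. Lists of 2000 peaks, which leave out suspension replicate 3, gave 404 collagen-only, 110 suspension-only and 583 shared regions. That setting put 3 lists against 2. The other divisions of these 5 lists into 3 and 2 gave 358 to 449 regions for the 3 lists and 85 to 141 for the 2. A −log10 q of at least 5 gave 1 collagen-only, 2 suspension-only and 33 shared regions, and presence in all 3 libraries gave 6, 0 and 6. Peaks over 50% of a region gave 143 shared and 5 suspension-only regions.

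The 22 collagen-only regions were narrow and ranked low by −log10 q within their lists, and most lay close to a long stretch without peaks. All positions are on hg19, and no annotation of that build was used, so what lies at them is not given. Highest by rank among the 6 with a peak in all 3 collagen libraries was chromosome 2 from 89851865 to 89852588, with a fold enrichment of 2.82 ± 0.315 (SD, n = 3). It was followed by chromosome 1 from 143541307 to 143541704 (3.45 ± 0.248), chromosome 20 from 29628543 to 29629157 (3.01 ± 0.361) and chromosome 21 from 10841541 to 10841895 (3.13 ± 0.238). The fifth was chromosome 16 from 46426874 to 46427129, where fold enrichment was only 1.80 ± 0.129 although pileup ran from 60.5 to 65.3 tags. It lay within 1 kb of a region with a peak in all 6 libraries, from 46427464 to 46428065. The leading region was on the same chromosome as another of these, from 89872084 to 89872875. Merging peaks within 1 kb gave 21 collagen-only regions. The remaining region with a peak in all 3 collagen libraries lay on chromosome 20 from 29825376 to 29825962 (3.17 ± 0.0746), and is named although it falls outside the rule. Peaks of all the collagen-only regions had a median width of 294 bp and a median percentile of 11.8 for −log10 q within their own lists. Regions recurring in both conditions had a median width of 617 bp in the collagen lists and a median percentile of 70.2. Of the 22 regions, 14 (63.6%) lay within 5 Mb of the longest peak-free span of their chromosome, against 705 of the 8686 recurring collagen regions with a suspension peak (8.12%; Fisher's exact test, two-sided, odds ratio 19.8, p = 1.04e-10). This test was chosen after the positions were seen, and neighbouring regions are not independent (5 of the 22 lay on chromosome 16), so its p is too small.

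The suspension-only regions had peaks in suspension replicates 1 and 2 and in no other library. The leading region, chromosome 14 from 91282177 to 91282784, had a fold enrichment of 5.30 in replicate 1 and 3.41 in replicate 2. Next by rank came chromosome 1 from 565153 to 565492, with 2.83 and 3.05. Chromosome 10 from 21784879 to 21786424 carried a peak of 1546 bp in replicate 1 and of 200 bp in replicate 2, with fold enrichments of 4.31 and 3.76. On chromosome 5, the region from 52284885 to 52285657 reached 4.59 and 3.73, and on chromosome 19 the region from 54640085 to 54640728 reached 4.00 and 3.12. Only 1 of the 9 lay within 5 Mb of the longest peak-free span of its chromosome.

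Called peaks differed more in number between the suspension libraries than between the conditions. Suspension replicate 1 had 16328 peaks over 17.9 Mb, suspension replicate 2 had 3089 over 1.14 Mb and suspension replicate 3 had 6 over 0.00272 Mb. The sources used here do not say whether the immunoprecipitation of suspension replicate 3 worked. From 27.4 M tags it gave 6 peaks, 0 of them at a −log10 q of at least 5, with an estimated 0.00525% of tags in peaks. It is counted as a replicate in the means, so the suspension SD cannot be read as variation of the mark alone. Since its 6 peaks lay in regions marked in every library, regions recurring in suspension were in effect those of replicates 1 and 2. Collagen replicates 1, 2 and 3 had 9807, 14000 and 6344 peaks, over 4.99, 10.9 and 2.71 Mb. The mean number of peaks was 6474 ± 8672 in suspension and 10050.3 ± 3834 in collagen (SD, n = 3 each), a difference of 3576 with an exact permutation p of 0.6. Genomic length under peaks was 6.33 ± 9.99 Mb in suspension and 6.20 ± 4.24 Mb in collagen (difference −0.126 Mb, exact permutation p = 1). Neither difference exceeded the spread between replicates, and all 5 group tests had a Benjamini-Hochberg adjusted p of 1. Both differences turned on settings and on single libraries: the difference in peaks was −1276 at a −log10 q of at least 5, 342 without suspension replicate 3 and 8503 without suspension replicate 1. The difference in length was 5.63 Mb without suspension replicate 1 and −3.29 Mb without suspension replicate 3.

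**Figure D1:**
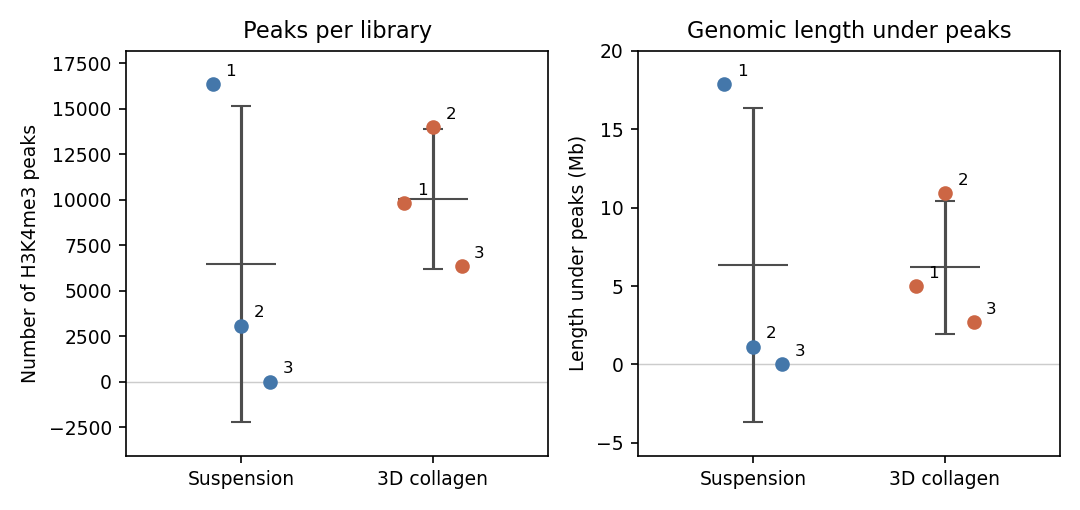
Number of H3K4me3 peaks (left) and genomic length under peaks in Mb (right) for each library, with points numbered by replicate, the group mean as a long horizontal line and 1 SD as the error bar (n = 3). Suspension libraries ran from 6 to 16328 peaks and collagen libraries from 6344 to 14000, and in suspension the SD was larger than the mean.

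Peaks were wider in the longer lists, apart from the 6 peaks of suspension replicate 3. The median width was 990 bp in suspension replicate 1, 329 bp in replicate 2 and 370 bp in replicate 3, against 455, 700 and 385 bp in collagen replicates 1, 2 and 3. Group means were 563 ± 370 bp in suspension and 513 ± 165 bp in collagen (SD, n = 3 each, exact permutation p = 1). Peaks of at least 2 kb numbered 1683 in suspension replicate 1 and 220 in collagen replicate 2, and there were 0 in each of the other libraries. The median fold enrichment was 4.23 in suspension replicate 1, 3.28 in replicate 2 and 1.90 over the 6 peaks of replicate 3. It lay between 3.32 and 3.58 in the collagen libraries. An estimated 9.07% of tags lay in peaks in suspension replicate 1, 0.417% in replicate 2 and 0.00525% in replicate 3. In collagen the estimates were 1.88%, 4.58% and 1.11% for replicates 1, 2 and 3. Tag totals were alike, at 28.1 ± 0.711 M in suspension and 28.7 ± 1.25 M in collagen (SD, n = 3 each, exact permutation p = 0.5). Over the 6 libraries, tag totals and numbers of peaks had a Pearson r of 0.574 (exact permutation p = 0.244) and a Spearman rho of 0.429 (exact permutation p = 0.419), both with an adjusted p of 0.419 over the 2 relations. Without collagen replicates 1 and 2, whose tag totals were farthest from the median, r was 0.713.

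By the Jaccard index, shared regions did not group the libraries by culture condition, but this index depends on list length. With shorter lists nested in longer lists, it cannot tell a grouping by condition from a difference in length. The mean Jaccard index of bases under peaks was 0.186 within conditions and 0.176 between them, a difference of 0.00991 (exact permutation p = 1, n = 3 each). The closest pair was suspension replicate 1 with collagen replicate 2, at 0.592, while suspension replicates 1 and 2 shared 0.0630. Collagen replicates 1 and 2 shared 0.422, replicates 1 and 3 shared 0.382 and replicates 2 and 3 shared 0.244. The difference was 0.169 without suspension replicate 1 and −0.109 without collagen replicate 1, and it was also below 0 without collagen replicate 2 (−0.0359) or 3 (−0.0713).

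**Figure D2:**
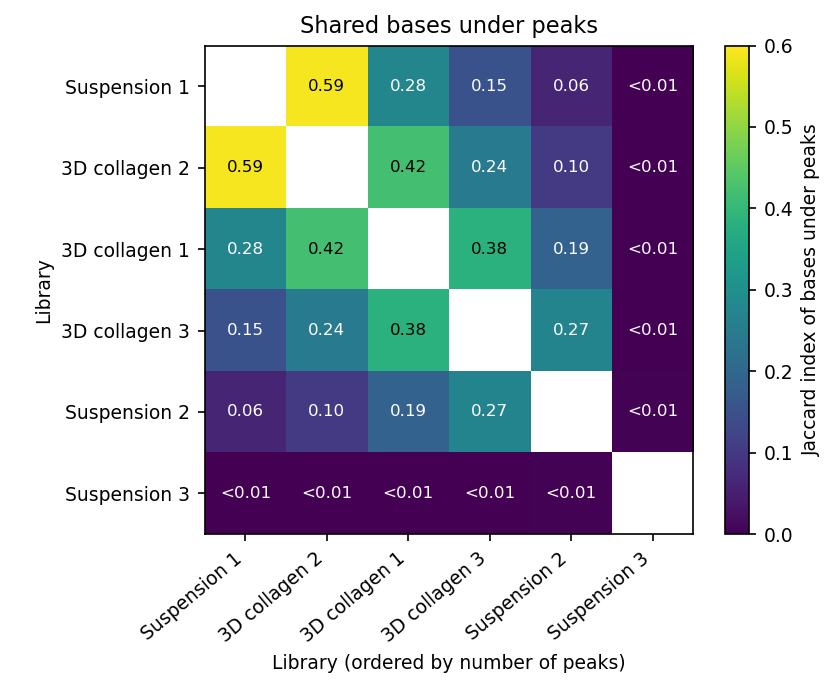
Jaccard index of bases under H3K4me3 peaks for each pair of libraries, ordered on both axes by number of peaks, with the colour scale from 0 to 0.6 and blank cells on the diagonal. The highest value, 0.592, joined suspension replicate 1 and collagen replicate 2, and similarity fell away with distance in list length.

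Shorter lists were nested in longer lists, whichever condition they came from. Suspension replicate 1 contained 99.2% of the peaks of collagen replicate 1, 98.5% of those of collagen replicate 2, 99.5% of those of collagen replicate 3 and 99.1% of those of suspension replicate 2. Collagen replicate 2 contained 97.9% of the peaks of collagen replicate 1 and 99.4% of those of collagen replicate 3. Among pairs without suspension replicate 3, the lowest share was 81.3% (95% interval 79.9 to 82.7), for suspension replicate 2 in collagen replicate 3, and shifted lists gave at most 1.08%. The strongest peaks of suspension replicate 1 were found more often than its weakest in each list but that of suspension replicate 3, which had none of the peaks of deciles 5 to 10. Among the strongest decile of suspension replicate 1 peaks by −log10 q, collagen replicate 2 had 100%, collagen replicate 1 had 97.4%, collagen replicate 3 had 90.3% and suspension replicate 2 had 63.6%. In the weakest decile the shares were 8.33%, 1.84%, 0.797% and 0.919%. The 4229 regions found in suspension replicate 1 alone, out of its 16253 regions, held peaks with a median width of 371 bp and a median −log10 q of 2.86. Its 2467 peaks found in 4 other libraries had a median width of 1579 bp and a median −log10 q of 12.6.

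**Figure D3:**
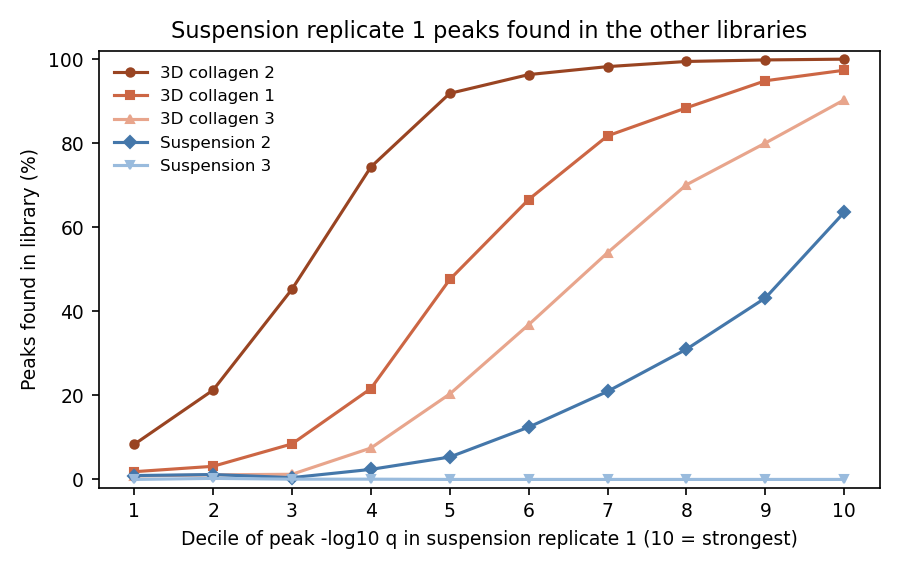
Percent of suspension replicate 1 peaks that overlapped a peak of each other library, by decile of −log10 q in suspension replicate 1 (10 is the strongest), with a line per library. In the strongest decile the shares were 100%, 97.4% and 90.3% for collagen replicates 2, 1 and 3 and 63.6% for suspension replicate 2, and suspension replicate 3 had 0%.

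A core of 2474 regions had a peak in every library except, for 2468 of them, suspension replicate 3. Where a library had several peaks in a region, only the one with the highest −log10 q was taken. At these regions the median width of that peak was 1576 bp in suspension replicate 1 and 344 bp in replicate 2. It was 616, 1032 and 474 bp in collagen replicates 1, 2 and 3. Median fold enrichment of the same peaks was 5.27 and 3.30 in suspension replicates 1 and 2, and 3.57, 4.18 and 3.60 in collagen replicates 1, 2 and 3. Across these regions, which are not independent replicates, Spearman's rho of fold enrichment ran from 0.449 to 0.627 for pairs of libraries between conditions and from 0.512 to 0.591 among collagen libraries, and was 0.439 for suspension replicates 1 and 2. Regions were ranked by the peak length of each library, summed over all its peaks in the region and averaged over libraries. Widest, at 2468 bp, was the region on chromosome 11 from 65623842 to 65629027. There the highest-scoring peak alone was 5103 bp in suspension replicate 1 and 384 bp in replicate 2, against 1221, 1682 and 967 bp in collagen replicates 1, 2 and 3. By the summed length this region was followed by chromosome 12 from 108953487 to 108957415, chromosome 8 from 67973270 to 67977651 and chromosome 12 from 122237682 to 122243046. The fifth lay on chromosome 6 from 157097726 to 157101720. Its highest-scoring peaks alone were 3995 and 989 bp in suspension replicates 1 and 2, and 943, 2087 and 336 bp in collagen replicates 1, 2 and 3. These 5 regions were chosen after their values were seen.

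The 6 regions present in all libraries were of another kind. They were the 6 peaks of suspension replicate 3, and 5 of them lay on chromosome 16, with pileup high and fold enrichment low. From 46385802 to 46386869 on chromosome 16, pileup ran from 125 to 134 tags over the 6 libraries and fold enrichment from 1.69 to 1.88. The others named by the rule were chromosome 16 from 46427464 to 46428065 (fold enrichment 1.58 to 1.75), from 46401183 to 46401753 (2.03 to 2.42) and from 33975068 to 33976011 (1.66 to 1.92), and chromosome 2 from 89872084 to 89872875 (2.41 to 3.04). By contrast, the median −log10 q of these regions in suspension replicate 1 was 3.23, against 7.73 for all peaks of that library.

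Chromosomes with more protein-coding genes held more peaks, apart from suspension replicate 3, which had 5 of its 6 peaks on chromosome 16. Across 23 chromosomes, which are not independent replicates, Pearson's r between the number of peaks and the number of protein-coding genes was 0.978 in suspension replicate 1 and 0.841 in suspension replicate 2, and 0.918, 0.974 and 0.912 in collagen replicates 1, 2 and 3. Spearman's rho was 0.969 and 0.842 in suspension replicates 1 and 2, and 0.918, 0.958 and 0.912 in the collagen replicates. Without the 2 chromosomes farthest from the median number of genes, r was 0.959 and 0.707 in suspension replicates 1 and 2, and 0.841, 0.949 and 0.837 in the collagen replicates. Peaks per gene in suspension replicate 2 ran from 0.105 on chromosome 19 to 0.214 on chromosome 16 among the autosomes. Chromosome X stood apart. Of its 544 peaks in suspension replicate 1, 23.3% were found in collagen replicate 1, 66.0% in collagen replicate 2, 16.4% in collagen replicate 3 and 3.13% in suspension replicate 2. For the 15761 autosomal peaks the shares were 52.1%, 73.8%, 37.0% and 18.6%. Median fold enrichment in suspension replicate 1 was 4.26 on chromosome X and 4.23 on the autosomes, while median pileup was 14.9 and 25.7 tags and median −log10 q 4.68 and 7.92. Chromosome 19 had the lowest autosomal share in collagen replicate 1 (44.7%) and chromosome 16 the highest (56.8%).

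**Figure D4:**
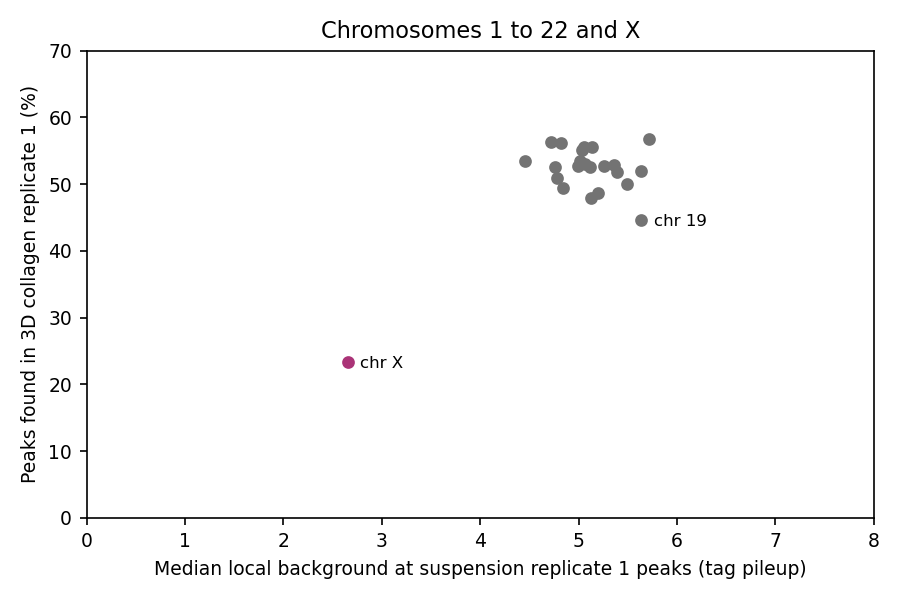
Percent of suspension replicate 1 peaks found in collagen replicate 1 (vertical axis) against the median local background, derived from pileup and fold, at the suspension replicate 1 peaks, in tag pileup (horizontal axis), with a point per chromosome for 1 to 22 (grey) and X (purple). Chromosome X lies at 23.3% and a background of 2.65, below the autosomes, which run from 44.7% to 56.8% and from 4.46 to 5.71.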

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

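Leaving out suspension replicates 2 and 3 together, leaving out peaks near long peak-free spans, and the counts of regions recurring in 1 group alone were chosen only after the data were seen; no alternative gave a p under 0.05, which 3 libraries against 3 cannot reach. The difference in number of peaks (3576) kept its direction under 10 alternatives and reversed to −1276 at −log10 q of at least 5; it was −6278 without suspension replicates 2 and 3, where the sign was set by the choice, since only the library with the longest list was left. Leaving out single replicates gave 342 to 8503. The difference in length (−0.126 Mb) reversed to 0.90 on the log2 scale and ran from −3.29 to 5.63 Mb as single replicates were left out. At −log10 q of at least 5, where suspension replicate 3 had no peaks, regions recurring in both groups numbered 33, collagen-only regions 1 and suspension-only regions 2, and those recurring in collagen or suspension alone numbered 1388 and 11 (5832 and 82 in the full lists; not subsets of these, since the shared regions fell from 2876). Requiring peaks over 50% of a region gave 143 regions recurring in both groups, 5 suspension-only, and 2438 and 45 recurring in collagen or suspension alone. Requiring all 3 libraries gave 6 in both groups, 6 collagen-only, 0 suspension-only, and 5483 and 0 recurring in collagen or suspension alone. Lists of 2000 peaks, without suspension replicate 3, gave 583, 404 and 110 regions in both, collagen-only and suspension-only, and 1051 and 311 recurring in collagen or suspension alone. Away from long peak-free spans 8 of the 22 collagen-only regions were left. Leaving out single replicates gave 7 to 6342 collagen-only, 0 to 75 suspension-only and 6 to 2876 shared regions, and 3027 to 9232 and 0 to 485 recurring in collagen or suspension alone. The similarity difference (0.00991) reversed to −0.00359 with lists of 2000 peaks and ran from −0.109 to 0.169 without single replicates. Counts rose under some of these settings and fell under others, and the cause was not tested. Deviations of same-numbered libraries correlated at −0.0544, −0.229 and −0.167. This cannot settle whether replicate numbers pair the samples, since the labels do not say and suspension replicate 3 had only 6 peaks. With the replicate number as a block the differences stayed at 3576 peaks (exact sign-flip p = 0.75, smallest possible 0.25) and −0.126 Mb (exact sign-flip p = 1), and same-numbered libraries across groups were less similar than others by a Jaccard difference of −0.0738, which is another quantity than the within-group excess; no suspension library correlated best with the collagen library of its own number. Alternatives on promoters and gene lists were not run, since no hg19 annotation was used. With lists that hold only called peaks, signal below the caller's threshold sets the limit on any statement of absence.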

Other observations

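The tests on the excess of regions recurring in collagen, on long peak-free spans and on equal-length lists in other divisions of the libraries were chosen only after the results were seen. Regions with a collagen peak and no suspension peak numbered 263, and most were seen in a single library: 180 in collagen replicate 2 alone, 47 in collagen replicate 1 alone and 14 in collagen replicate 3 alone. Another 16 regions were seen only in suspension replicate 2. Within the collagen lists, peaks at regions recurring in collagen and present in 1 suspension library had a median percentile of 47.2 for −log10 q and a median width of 496 bp, between those of the regions recurring in both conditions and those of the collagen-only regions. In collagen replicate 1, 1 peak lay on the mitochondrial genome.

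Regions recurring in collagen alone, with a peak in at least 2 collagen libraries and fewer than 2 suspension libraries, numbered 5832, against 82 in the reverse direction. As single libraries were left out, the former ran from 3027 (without collagen replicate 2) to 9232 (without suspension replicate 1). The reverse count ran from 0 (without suspension replicate 1 or 2) to 485 (without collagen replicate 2). Lists of 2000 peaks gave 1051 against 311. There, peaks in at least 2 lists were required of 3 collagen lists but of only 2 suspension lists, which is harder to reach in suspension. Lower sequencing depth, counted as total tags, is argued against. Suspension tag totals were on average 1.98% below those of collagen (−1.98%), and the lower of suspension replicates 2 and 3 differed from the collagen mean by −4.48%. Duplicate tags were kept in these totals, so a lower number of distinct fragments was not tested. The appearance of marks at regions unmarked in suspension and low enrichment in suspension replicates 2 and 3 both stay open. Of the recurring collagen regions, 0.253% lacked a suspension peak, but without suspension replicate 1 the share was 68.7% (6342 of 9238). Suspension replicate 1 had a peak at 99.5% of the 5832 regions, so those were marked in that 1 suspension library. This does not decide between the explanations, since that list held at least 98.5% of every other list. The 10 splits of the 6 libraries are too few for a share under 0.05; the real excess was 5750, the highest of the others was 9490, and 6 of the 10 splits, the real one included, gave an excess as large. In lists of 2000 peaks, the real division of the 5 libraries long enough gave 404 regions in at least 2 collagen libraries and no suspension library, and the 9 other divisions into 3 and 2 libraries gave 358 to 449; the reverse counts were 110, and 85 to 141.

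Regions recurring in collagen without a suspension peak (22) and those recurring in suspension without a collagen peak (9) came to 31. Most did not separate the groups completely: with a peak required in every library of the group, the counts were 6 and 0. The 10 splits are too few for a share under 0.05, with 31 for the real groups and 5697 for the highest other split, and 8 of the 10 splits, the real one included, gave as many. That highest split set suspension replicates 2 and 3 and collagen replicate 3 against the longer lists, which points to a structure of the libraries by list length. The splits for similarity are likewise too few, with a real difference of 0.00991 and a highest other value of 0.135, and 10 of the 10 splits, the real one included, were as large in absolute value.

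Chromosome X peaks of suspension replicate 1 were found less often in the other libraries than autosomal peaks were. Median local background at these peaks, derived from the deposited pileup and fold, was 2.65 on chromosome X and 5.16 on the autosomes, a difference of −48.6%. When autosomal peaks were matched by decile of −log10 q, the share of chromosome X peaks found in collagen replicate 1 was 1.15 times the autosomal share (95% bootstrap interval 0.980 to 1.31), so the lower share may follow from weaker peaks on a chromosome with fewer tags. The matched ratio was 1.24 in collagen replicate 2, 1.85 in collagen replicate 3 and 0.923 in suspension replicate 2. The design names no group that bears on chromosome X, and no biological explanation was tested.

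The collagen-only regions clustered, with 63.6% within 5 Mb of the longest peak-free span of their chromosome against 8.65% of all regions. With spans drawn without these 22 regions and without the 6 present in all libraries, the count within 5 Mb was again 14, and 5 of those 6, all on chromosome 16, lay as near, so closeness to such spans is not particular to collagen-only regions. Repeated sequence near such gaps, where tags from many copies can pile up, is a candidate explanation. The longest span is a poor stand-in for a centromere on several chromosomes: on chromosome 13, where 2 regions counted as near, it ran from 53228199 to 60737168, and on chromosome 2 from 48668772 to 53994399, so that the leading collagen-only region counted as far. Mappability and sequence were not examined, and a true gain of the mark at the 8 other regions was not tested.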
